A study of Homo sapiens with 3 samples.

How the data were processed

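Total RNA of 3 Caco-2 cultures, a control with a non-target short hairpin RNA (n = 1) and 2 lines with different hairpins against OCC-1 (OCC-1 knockdown, n = 2), was measured on oligonucleotide expression arrays with 49395 probe sets. Groups were taken from the genotype label of each sample. Per the labels, the cultures were lentivirally transduced and selected, RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. The authors' deposited values were 1 intensity per probe set and array on a linear scale, and RMA was named in the submitters' processing notes without a version or settings. A log2 scale had been foreseen before the data were examined, but the deposited intensities run from about 50.1 to 19619 and were therefore converted to log2 here. The arrays' background control probe sets kept intensities from 51.3 to 2307 in the control, where the lowest value on the array was that of 1 of them. Background thus appears to remain in the intensities, which would make fold differences smaller than those of the transcripts. Whether a background was subtracted, and how the arrays were scaled, is not given in the sources used here. No further normalization was applied. No pair of arrays held identical values, and the median log2 difference over probe sets between 2 arrays was at most 0.04.

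Probe sets were named from the platform annotation, with symbols updated by gene identifier through NCBI RefSeq gene tables for assembly GRCh38.p14. Of the probe sets 44988 had 1 gene symbol, 1832 had several, 2473 had none and 102 were array controls. Of the first group 44961 were looked up by identifier and 0 symbols changed. Probe sets with several symbols were not named. For each of 18132 genes the probe set with the highest mean over the 3 arrays was used, and genes with a mean below the median of all probe sets (log2 7.52, intensity 184) were left out, which left 11329. Where other probe sets of a gene are given, except for ELAVL1, those above the same threshold are meant, without 38 that had the same values on all arrays as another probe set of their gene. Gene length and the number of protein-coding genes within 500 kb on each side were computed from gene positions in the same RefSeq table, and no coordinates are reported. Both were found for 99.9% of the genes.

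The main rule was one of size, at least 1.5-fold from control the same way in both lines, since 1 array per line allows no test of a single line. Because both lines were set against the same control, each array was also used as the reference in turn, and 100 draws of unchanged arrays with a shared control were simulated, with noise resampled from the difference between the knockdown arrays within bins of intensity. In addition limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment) compared the 2 knockdown arrays with the control, with 1 residual degree of freedom and 6.96 in total after moderation. The labels do not say that the lines are repeats of a single culture, so the p-values measure only the spread between these 2 arrays with different hairpins, and the lone control is assumed to vary like them. Gene lists were described by their median difference and its percentile among 10000 random lists of the same size matched in 20 bins of mean level. A list was called apart only at or under 2.5 or at or over 97.5 in both lines on the same side, and lists with fewer than 5 genes are given as values. Percentiles describe these arrays and are not p-values. Intervals of ratios between probe sets are 95% bootstrap intervals over genes. The simulations of this ratio gave all probe sets of a gene 0.81 of its measured difference plus noise resampled as above, without background or with one of 104.2, and picked genes by the same size rule. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

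Both procedures were tested on simulated data for the comparison of knockdown with control over 11329 genes. Of 100 genes changed by log2 0.7 the size rule found 78 and limma 100, and of 100 changed by 1.2 both found 100. Of 11129 unchanged genes the size rule called 0 and limma 17, with the control's noise also taken from the knockdown arrays. A simulated list of 30 genes moved by 0.3 reached percentile 100, and of 100 unmoved lists 8% lay outside the bounds in a single line. Because the real differences of the 2 lines correlate more than simulated ones, the share of random lists outside the bounds in both lines was counted on the real differences, after the list results were seen.

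The genes named were fixed by a rule before the data were examined. It took OCC-1 and ELAVL1, the 12 higher and 12 lower genes with the largest smaller difference of the 2 lines, the 3 smallest limma p-values each way, up to 4 members per described list (3 with values where none passed), and the 5 genes most different between the lines each way. Genes of the hnRNP and peroxisome lists were chosen after their values were seen. Alternatives were a fold of 1.3 or 2, no filter or one at the 75 percentile, median centring, quantile normalization and cyclic loess, a floor at the 25 percentile, the mean of all probe sets, each line alone, the mean of both lines, and for limma an intensity trend and an adjusted p of 0.1. Chosen after seeing the data were normexp background correction with an offset of 50, the requirement that every probe set of a gene pass 1.3-fold, and limma together with the size rule.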

Results

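Gene expression was measured in Caco-2, an established line of human colorectal cancer cells that can form an enterocyte-like layer, after the transcript OCC-1 (gene symbol C12orf75) had been depleted by RNA interference. The 3 arrays held total RNA from 1 line with a non-target short hairpin RNA (the control) and from 2 lines with different short hairpin RNAs against OCC-1, here called line 1 and line 2. According to the labels, each line had been grown with 20% serum and selected with puromycin at 1 µg per ml for 5 days, and RNA was taken 24 hours after the drug was removed. Each array gave an intensity for 49395 probe sets, with medians of 185.5 in the control, 182.5 in line 1 and 183.6 in line 2. Across all probe sets the log2 intensities of lines 1 and 2 correlated with r = 0.998, and those of the control with r = 0.992 against line 1 and r = 0.993 against line 2. Genes are not independent replicates, and 1 array per line gives no replicate check of any single line, so the number of arrays limits the precision of every value.

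The first comparison asked whether the targeted transcript was lower in the lines that carried the OCC-1 hairpins. OCC-1 had an intensity of 1219 in the control, 518 in line 1 and 397 in line 2, which is 42.5% and 32.5% of control. The log2 difference from control was -1.43 ± 0.27 (SD, n = 2 knockdown lines), and OCC-1 had the lowest mean difference of the 11329 genes above the intensity filter. Its level was read by 1 probe set. Background appears to remain in the intensities, which would make the depletion look smaller than it was. With normexp background correction, added after seeing the data, the difference was -1.45. That correction adds an offset of 50 back to every value, so it cannot show how much the remaining background hides.

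The study's authors have tied OCC-1 to the stability of HuR, the RNA-binding protein encoded by ELAVL1, and the mRNA of this gene was therefore looked at next. The brightest ELAVL1 probe set did not differ, with 974 in the control, 974 in line 1 and 992 in line 2. The other 4 ELAVL1 probe sets, the dimmest of which lay below the intensity filter, went different ways. One was at 81.2% and 76.0% of control in lines 1 and 2, another at 113.5% in both lines, and the remaining pair at 104.4% and 104.1% and at 107.9% and 105.7%. No ELAVL1 probe set was 1.5-fold from control. Protein levels were not measured by the arrays.

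**Figure D1:**
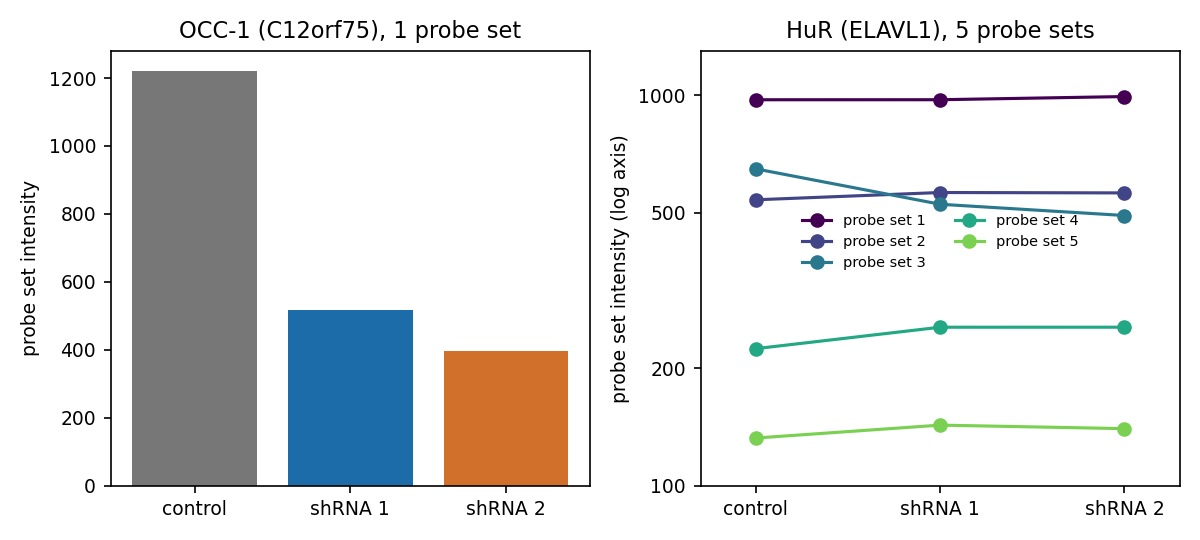
Probe set intensity on the 3 arrays (x axis: control, OCC-1 shRNA line 1, OCC-1 shRNA line 2; 1 array each), as bars for the OCC-1 probe set on a linear axis and as connected points for the 5 ELAVL1 probe sets on a log axis. OCC-1 stood at 1219, 518 and 397, while the brightest ELAVL1 probe set stayed between 974 and 992.

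The series took genes that differed from control with both hairpins as OCC-1-regulated, and the same overlap was formed here by size, at least 1.5-fold the same way in both lines. More genes were higher than lower. Of 11329 genes, 154 were higher and 18 lower in both lines, and 0 were higher in 1 line and lower in the other. Line 1 taken alone gave 219 higher and 24 lower genes, and line 2 taken alone 212 and 46. Independent lists of these lengths would share 4.10 higher and 0.097 lower genes. The lists of lines 1 and 2 are not independent, because both use the same control array, so a larger overlap is expected without any effect. In 100 simulations of unchanged arrays that share a control, 0 genes passed in either direction. Their noise came from the 2 knockdown arrays, so they do not cover a control array that deviates more than these. The rule left 8 higher and 4 lower genes at 2-fold and gave 602 and 106 at 1.3-fold.

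The 12 genes with the largest shared decrease included OCC-1 itself. CST1, which encodes the secreted protease inhibitor cystatin SN, was 2.05-fold lower in line 1 and 3.02-fold lower in line 2. TFF1, a secreted trefoil peptide of the mucosa, was 2.01-fold and 2.10-fold lower. GPX2, the gastrointestinal glutathione peroxidase, was 2.01-fold and 2.14-fold lower, and TSPAN8, a membrane tetraspanin, was 2.12-fold and 1.98-fold lower. The aldo-keto reductases AKR1C1 (1.76-fold and 1.80-fold) and AKR1C2 (1.68-fold and 1.58-fold) were lower together, but these near-identical paralogs can share probes and are not certain to be separate results. APOD, a lipid-binding apolipoprotein, was 1.59-fold and 2.17-fold lower. DPYSL3, FLRT3, FABP7 and TM4SF4 were 1.58-fold to 1.74-fold lower in line 1 and 1.58-fold to 1.68-fold lower in line 2. For 7 of the 18 lower genes another probe set passed the intensity filter, and all 9 such probe sets were lower in both lines, 3 of them by at least 1.5-fold. These 3 belonged to CST1, AKR1C1 and APOD.

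The 12 genes with the largest shared increase came from varied processes. TMED5, a cargo receptor of the early secretory pathway, was 2.29-fold higher in line 1 and 2.39-fold higher in line 2. SNAP23, a membrane fusion protein, was 2.16-fold and 2.29-fold higher. PTPRF, a receptor tyrosine phosphatase, was 2.17-fold and 2.19-fold higher. The homeobox factor HHEX was 2.31-fold and 2.11-fold higher, the phospholipid hydrolase ABHD3 2.10-fold and 2.17-fold, and the thiamine transporter SLC19A2 2.19-fold and 2.07-fold. RSL24D1, a ribosome assembly factor, was 2.05-fold and 2.18-fold higher, and ITIH2, a plasma protein heavy chain, 2.02-fold and 2.10-fold. ATP5MC1, which encodes a subunit of the mitochondrial ATP synthase, was 2.05-fold and 1.99-fold higher, and the chromatin reader ZMYND8 1.97-fold and 2.02-fold. MAD2L1 of the spindle checkpoint was 1.95-fold and 2.09-fold higher, and the antiproliferative gene TOB1 1.95-fold and 1.93-fold.

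Other probe sets of the higher genes seldom showed differences of that size. For 104 of the 154 higher genes another probe set passed the filter, and of these 217 probe sets 163 were higher in both lines but only 18 by at least 1.5-fold. Their median log2 difference was 0.18 in line 1 and 0.14 in line 2. TMED5 was an example, with 4 other probe sets at a median of 0.40 and 0.22, as were PTPRF, with 3 at 0.32 and 0.30, ZMYND8, with 5 at 0.17 and 0.11, SNAP23, with 3 at 0.14 and 0.19, and TOB1, with 1 at 0.30 and 0.07. The 2 other probe sets of MAD2L1 had medians of 0.72 and 0.70, and that of ABHD3 0.62 and 0.58. HHEX, SLC19A2, ITIH2 and ATP5MC1 had no other probe set with values of its own above the filter. With the mean of all probe sets of each gene, 44 genes were higher and 9 lower, of which 38 and 9 were among the 154 and the 18. Of the genes named above, TMED5, PTPRF, SNAP23, ZMYND8 and TOB1 were then no longer called, nor were APOD, FLRT3, DPYSL3 and AKR1C2, and FABP7 fell below the filter.

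**Figure D2:**
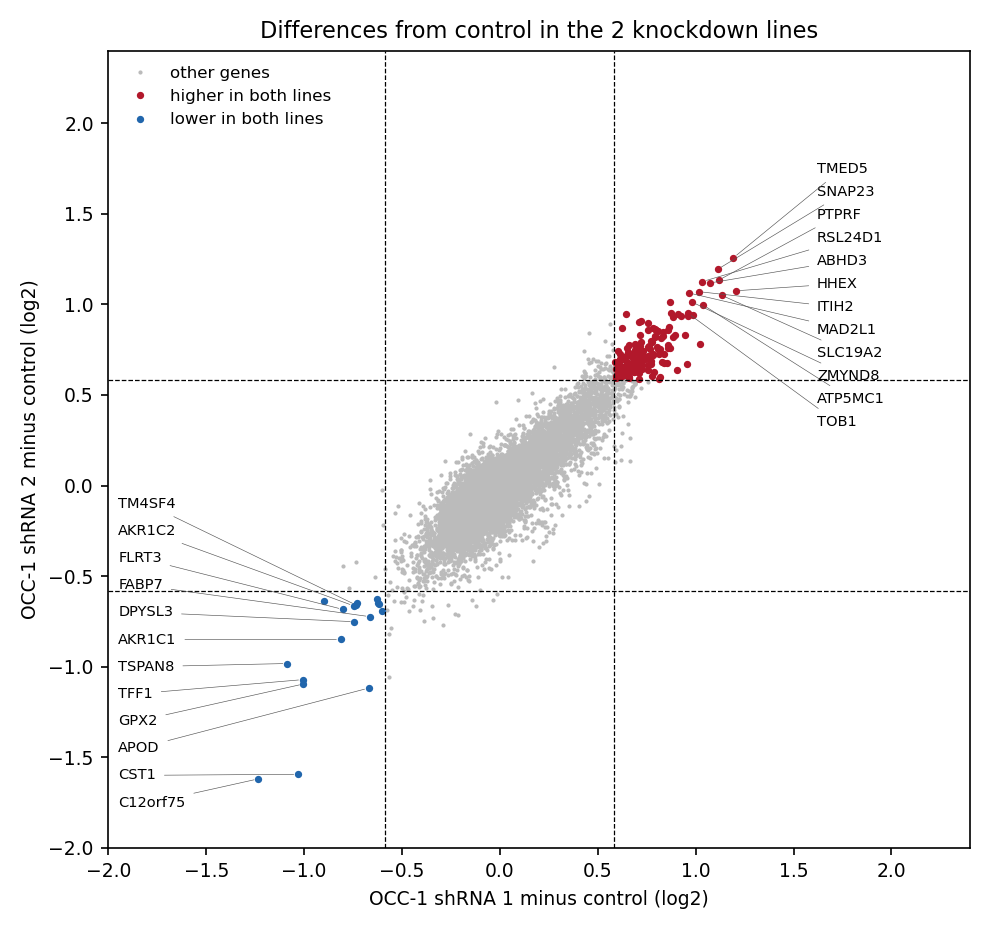
Log2 difference from control in line 1 (x axis) and line 2 (y axis) for 11329 genes, each point a gene, with the 154 genes higher in both lines in red, the 18 lower in both in blue, and dashed lines at 1.5-fold. The 12 genes with the largest shared difference each way are named, and no gene lies past 1.5-fold in opposite directions.

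**Figure D3:**
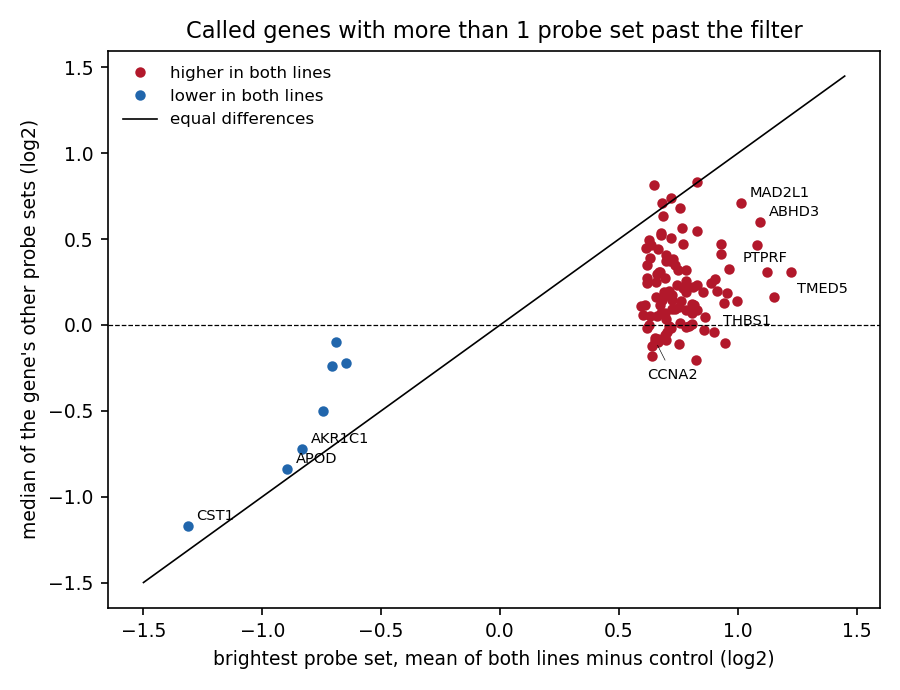
For called genes with another probe set above the filter (104 higher in red, 7 lower in blue), the log2 difference from control of the brightest probe set, as the mean of both lines, is on the x axis and the median over the gene's other probe sets on the y axis; the solid line marks equal values. Most of the red points lie far below the line, with a median over the other probe sets of 0.17 against 0.72 for the brightest.

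Both comparisons used the same control array, so each array was also taken as the reference in turn. With the control as reference 172 genes lay 1.5-fold away the same way on both other arrays, against 0 with line 1 and 1 with line 2 as reference. With line 1 or line 2 as reference, a gene can pass only if these lines are themselves 1.5-fold apart, as 1 gene was. The low counts thus show that the lines were alike, and cannot tell a deviating control array from an effect of the knockdown. Across genes, the differences from control in the 2 lines correlated with r = 0.878 and rho = 0.823, where simulated unchanged arrays that share a control gave 0.499 and 0.477. The covariance was 0.0441 against a simulated 0.00594, which leaves 0.0381. The differences had the same sign in 82.3% of genes, against 66.4% in the simulation. With a single control array the control could not be split, so part or all of the excess may come from the shared control. The simulated values assume that the control varies like the knockdown arrays.

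In limma, which treated the 2 lines as 1 group, 1438 of 11329 genes passed an adjusted p of 0.05, with 1091 higher and 347 lower in the knockdown lines. All 154 higher and all 18 lower genes of the overlap were among them. The smallest p-values belonged to TMED5 (log2 difference 1.22 ± 0.08 SE, limma adjusted p = 0.003), PTPRF (1.13 ± 0.07 SE) and SNAP23 (1.15 ± 0.08 SE) among the higher genes. Among the lower genes they belonged to TFF1 (-1.04 ± 0.08 SE), GPX2 (-1.05 ± 0.08 SE) and TSPAN8 (-1.03 ± 0.08 SE), with the same adjusted p. OCC-1 ranked 60 by p (adjusted p = 0.0049), with an SD of 0.27 between its 2 lines. Most genes that passed had small differences, with a median of 1.33-fold. The lone control is assumed to vary like the knockdown arrays. Setting line 1 or line 2 against the other pair cannot check this, because the spread is then that between the control and a knockdown array.

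The lines differed little from each other. FYTTD1, an mRNA export factor, was the only gene at least 1.5-fold apart, being 1.51-fold higher in line 1 than in line 2, where it was at 0.65 of control. The next genes higher in line 1 were CHI3L1, a secreted chitinase-like protein, at 1.499-fold, RASD1 at 1.499-fold, CST1 at 1.48-fold and the peroxisomal racemase AMACR at 1.46-fold. Higher in line 2 than in line 1 were the efflux pump ABCG2 by 1.49-fold, the complement gene C5 by 1.40-fold, the iron exporter SLC40A1 by 1.35-fold, C1QL1 by 1.34-fold and the actin-binding gene TAGLN by 1.33-fold. Across genes, the SD of the log2 difference was 0.11 between the 2 lines, and 0.22 between each line and the control. No gene was 2-fold higher than control in 1 line and 2-fold lower in the other.

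Gene lists fixed before the data were examined gave a view of groups. Of 53 lists 49 had at least 5 genes above the filter, and 5 of these had a median apart from random lists of similar intensity in both lines, 1 of them high and 4 low. Random lists of the same sizes and intensities, drawn from the measured genes, lay outside these bounds in both lines on the same side in 1.86% of draws, which amounts to 0.91 of 49 lists. Genes of a real list can vary together and some lists share members, which the random lists do not copy. The value of 0.91 may thus be too low a background for the 5 lists.

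The high list held AU-rich mRNAs described as HuR targets, with a median of 0.10 in line 1 and 0.09 in line 2 over 33 genes (percentiles 98.1 and 98.8). For the mean of both lines the list had a median of 0.06 (percentile 95.1), within the bounds. Its members IGF1R, the insulin-like growth factor receptor (1.83-fold and 1.94-fold), THBS1, the matrix protein thrombospondin 1 (2.03-fold and 1.72-fold), and CCNA2, cyclin A2 (1.58-fold and 1.56-fold), were higher in both lines, 0 were lower, and 30 were neither. For none of the 3 did another probe set reach 1.5-fold: the other CCNA2 probe set lay at -0.10 in both lines, those of THBS1 at a median of 0.08 and -0.15, and those of IGF1R at 0.17 and 0.23. In limma 11 of the 33 rose and 1 fell over all genes tested, and 13 rose and 2 fell adjusted over the list alone. The list was not apart in both lines with all genes kept (percentiles 92.4 and 86.7) or after cyclic loess (97.3 and 99.7). Against random lists that also matched gene density and gene length, the percentile in line 1 was 96.8.

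The list of metallothioneins, small metal-binding proteins, also named the zinc exporter SLC30A1, which is not one of them. This list had the lowest median among lists with at least 5 genes, -0.32 in line 1 and -0.28 in line 2 over 7 genes (percentiles 0 and 0.05). MT2A was 1.66-fold and 1.57-fold lower, and the other 6 did not reach 1.5-fold in both lines. In limma 4 fell over all genes tested and 5 adjusted over the list alone. Metallothionein genes have close sequence copies that array probes may not separate, and the other MT2A probe set was lower by less, at -0.15 and -0.05.

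Enterocyte brush border and digestion genes had medians of -0.16 and -0.12 over 30 genes (percentiles 0 and 0.22). GUCA2A, the hormone guanylin of gut epithelium, was 1.54-fold and 1.55-fold lower and was the only member called by size. In limma 4 fell over all genes tested and 5 adjusted over the list alone, and 0 rose. Goblet cell genes had a median of -0.17 in line 1 but were within the bounds in line 2 (percentile 12.4), with SPINK4 at 0.71 and 0.75 of control and ZG16 at 1.21 and 1.203. Intestinal transcription factors were not apart, although GATA6 was 1.58-fold and 1.71-fold higher.

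Interferon-stimulated genes had medians of -0.12 and -0.20 over 24 genes (percentiles 1.32 and 0), with 0 called by size. PSMB8, an immunoproteasome subunit, was at 0.76 and 0.64 of control, the ubiquitin-like ISG15 at 0.80 in both lines and the transcription factor IRF9 at 0.82 and 0.77. In limma 3 fell over all genes tested and 7 fell and 1 rose adjusted over the list alone. Against random lists that also matched gene density and gene length, the percentile in line 1 was 7.25. TGF-beta and BMP target genes had medians of -0.18 and -0.14 over 12 genes (percentiles 0.13 and 2.34), but the list was not apart in line 2 with the mean of all probe sets (percentile 5.75). Its members went both ways, with ID1 at 0.71 and 0.75 of control, BAMBI at 0.69 and 0.81, and CCN2 at 1.41 and 1.52. In limma 2 of the 12 rose and 2 fell, over all genes tested and adjusted over the list alone.

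Among the lists that were not apart, G2/M and mitosis genes had 4 of 39 members higher in both lines, which were MAD2L1, CCNA2, NUSAP1 (1.71-fold and 1.52-fold) and ANLN (1.53-fold and 1.52-fold). The other probe sets of NUSAP1 (medians 0.21 and 0.13) and ANLN (0.10 and 0.14) were below that size. G1/S and DNA replication genes had 0 of 42 called and medians of 0.00 and -0.01. Hepatocyte-like secreted proteins had ITIH2, AHSG (1.56-fold and 1.64-fold) and SERPINC1 (1.53-fold and 1.60-fold) higher, with the list median high in line 1 (percentile 99.7) and not in line 2 (69.9). NRF2 target genes had AKR1C1 and AKR1C2 lower and 16 of 18 neither, with medians of -0.05 in both lines. The machinery of HuR ubiquitination had 0 of 10 called, with RBX1 at 1.48-fold and 1.40-fold. The other AU-rich-element binding proteins had 0 of 9 called, with TIA1 at 1.504-fold and 1.40-fold. Wnt target genes (0 of 20 called), p53 target genes (0 of 15) and anti-apoptotic genes (0 of 8) were not apart in both lines either. The 8 neighbours of OCC-1 on its chromosome had medians of 0.02 and -0.01.

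Markers of other cell types were also checked. Fibroblast genes (medians 0.02 and 0.01 over 9) and leukocyte genes (-0.08 and -0.05 over 6) were not apart, and 4 endothelial genes had medians of -0.09 and 0.01. LYZ, which is in the leukocyte and the Paneth cell lists, was the only one of these markers called, at 1.94-fold and 1.59-fold higher, but its other probe set lay at 0.38 and 0.06 and it was not called with the mean of all probe sets.

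**Figure D4:**
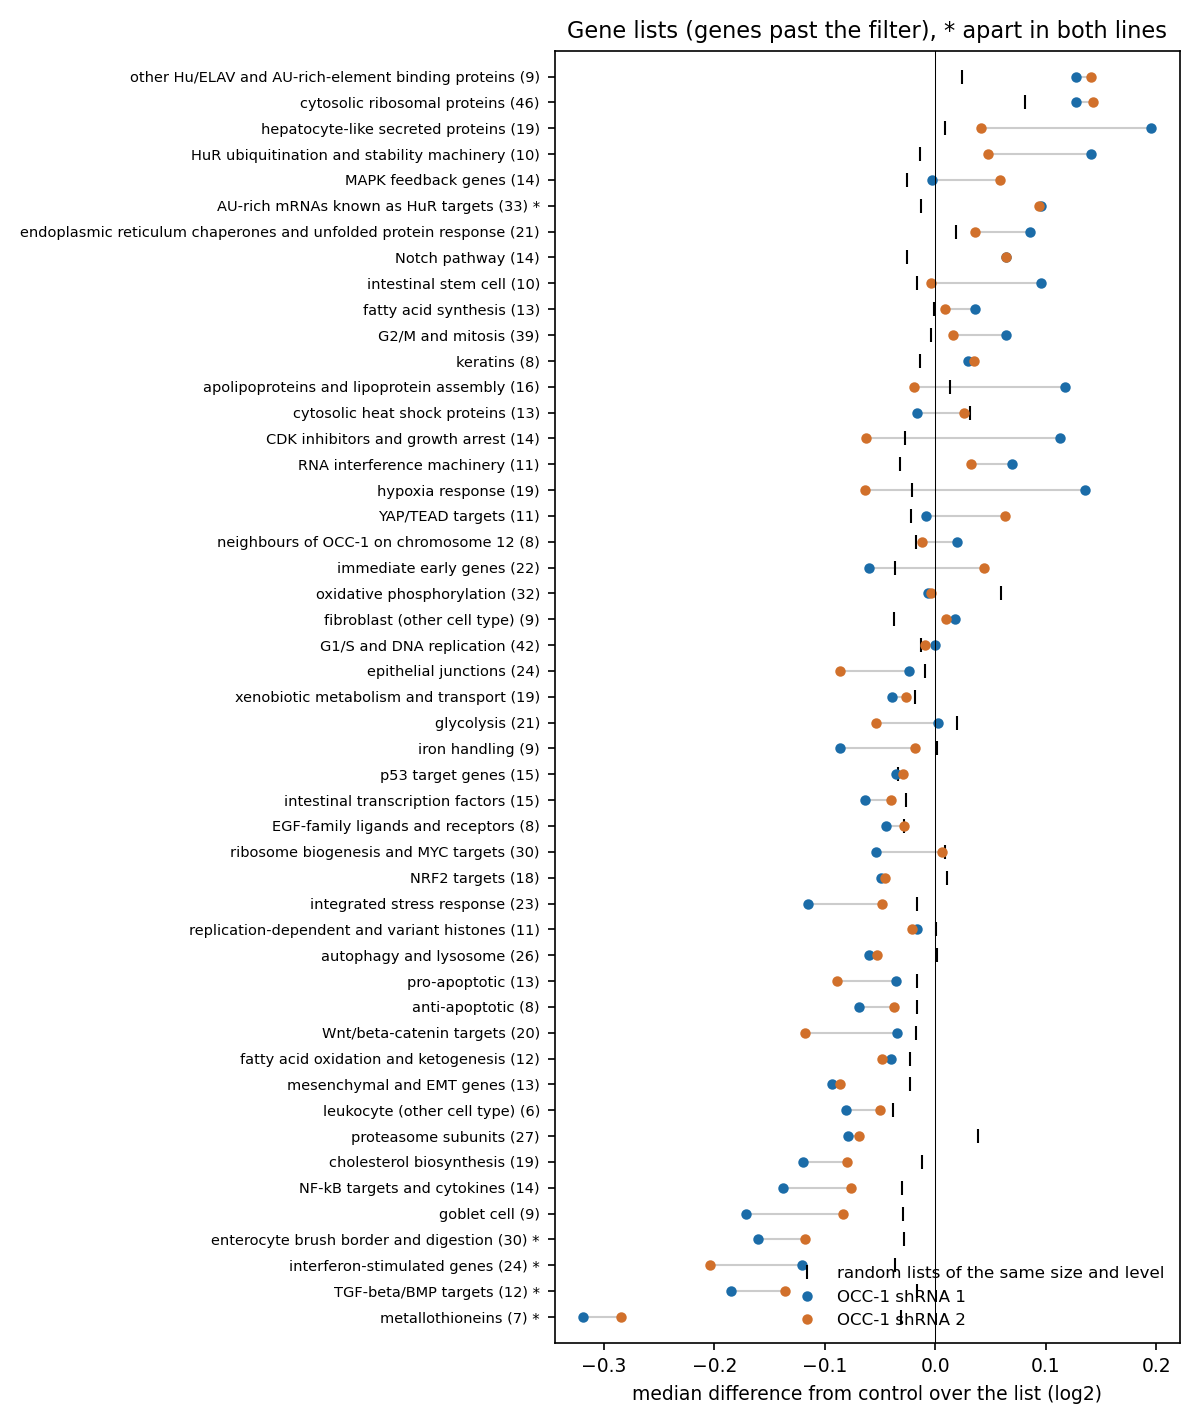
Median log2 difference from control (x axis) over the measured genes of each list with at least 5 genes above the filter (y axis, with that number of genes), for line 1 in blue and line 2 in orange; black ticks mark the median of random lists of the same size and intensity. Metallothioneins lie lowest at -0.32 and -0.28, and stars mark the 5 lists apart in both lines.

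The arrays differed in a way that ran along the base composition of probes, in the same direction in both lines. The 23 background control probe sets, whose names give the number of G or C bases per probe, had log2 differences from control in line 1 that ranged from 0.06 with few such bases to -0.37 with many. In line 2 the extremes were 0.04 and -0.23. Genes followed a related pattern, since across 11318 genes the mean difference from control correlated with the number of protein-coding genes within 500 kb at rho = -0.33. Of the 2830 genes with the fewest such neighbours 70 were higher and 7 lower in both lines, and of the 2830 with the most 6 were higher and 0 lower. The higher genes named above were thus called on arrays that also differed along gene density.

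**Figure D5:**
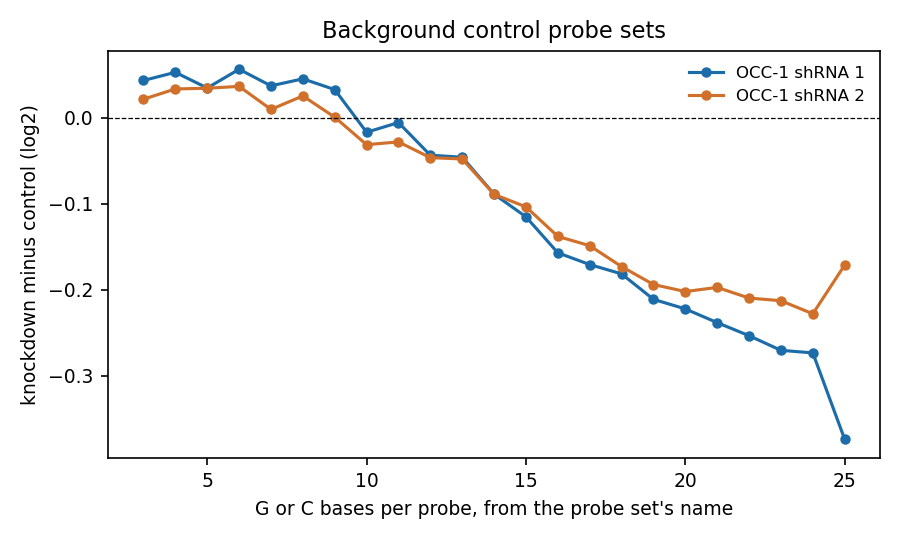
Log2 difference from control (y axis) of the 23 background control probe sets by the number of G or C bases per probe (x axis), with line 1 in blue and line 2 in orange; each point is a probe set on a single array. In both lines the values go from above 0 with few such bases to below 0 with many, reaching -0.37 in line 1 and -0.23 in line 2.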

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

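In this part the probe set, background and base composition tests were chosen after the results were seen. Probe sets outside the gene comparison also differed from control. Of 1975 probe sets above the filter with no gene or several genes, 33 were at least 1.5-fold higher in both lines and 0 were lower. Beside this, 154 of the 11329 genes were higher and 18 lower, so a larger share than among genes was not tested. A control probe set for dap, a bacterial transcript that can be added to samples before labelling, was higher on both knockdown arrays, by 1.302-fold on the lower of the pair, while the 5 other dap probe sets ranged from 0.97 to 1.197 of control in line 1 and from 1.03 to 1.44 in line 2, and the matching probe sets for other such transcripts were at 0.99 and 1.00 of control (lys), 1.22 and 1.18 (phe), and 0.90 and 0.95 (thr). Some control probe sets of other kinds moved by similar amounts, so the dap shift is not isolated. A cre probe set was at 1.29 and 1.33 of control. The other cre probe sets ranged from 1.055 to 1.155 in line 1 and from 1.06 to 1.16 in line 2. A bioD probe set was at 1.21 in both lines. The other bioD probe sets ranged from 0.92 to 0.98 in line 1 and from 0.94 to 1.02 in line 2. An 18S ribosomal RNA probe set was at 1.35 and 1.21, and the other 18S probe sets were also higher in both lines. For cre and bioD, probe sets of the same transcript thus differed.

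In the excess of higher over lower genes, 154 against 18, other probe sets of the higher genes shifted by 0.27 of the shift of the brightest (median over 104 genes, 95% interval 0.18 to 0.33), or 0.32 over the 73 genes with another probe set less than 1 log2 dimmer. Picking genes by the brightest probe set lowers this ratio by itself, to 0.90 in simulations with 1 shift per gene and 0.76 with background added. These simulations took noise from the knockdown arrays only, and picked 51.8 and 30.3 genes on average against 104 measured. They do not cover noise of the control array at single probe sets, so such picking is not excluded as the source of the low ratio. Much of the size may belong to single probe sets, through hybridisation or unread isoforms, but this was not settled. For the lower genes the ratio was 0.67 (0.34 to 0.89 over 7 genes), which leaves this open. A higher or lower background is argued against as the source, since background control probe sets reached a mean difference of 0.047 at the highest and -0.27 at the lowest, short of the 0.58 that 1.5-fold needs. The base composition of probes stays open for the higher genes, because differences followed gene density at rho = -0.33 but probe sequences were not used here. An effect of OCC-1 depletion is untested against these, since the control condition was on a single array.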

How the results depend on the processing

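The normexp, every-probe-set and limma-with-size settings were chosen after seeing the data. No called result reversed, while ELAVL1, which was not called, went from 0.01 to -0.01 after quantile normalization. The cause of the shifts below was not tested unless the setting itself sets the number. OCC-1 lay between -1.62 and -1.24 with each line alone. The 154 higher genes became 8 at 2-fold, 602 at 1.3-fold and 44 with the mean of all probe sets, and stayed between 130 and 219 under the other settings that kept all genes or filtered by intensity. The 18 lower genes became 4, 106 and 9 under these settings, 11 with the stricter filter, and 24 to 46 with each line alone. Every probe set above the filter passed 1.3-fold for 17 of the 104 higher and 3 of the 7 lower genes that had more than 1, and genes with a single probe set were not counted. The limma count of 1438 became 2208 without the filter, 2466 at an adjusted p of 0.1 and 172 with the size rule. The 172 genes with the control apart became 53 with the mean of all probe sets and 12 at 2-fold, and the correlation of 0.878 became 0.852 without the filter and 0.867 with the mean of all probe sets. The 1 gene between lines became 0 with the mean of all probe sets and 0 at 2-fold, and the 5 lists apart became 6 to 12 with each line alone, 12 without line 2. Of 41 named genes called in both lines, 41 stayed called after median centring, cyclic loess and normexp, 38 after quantile normalization, and 20 of 40 with the mean of all probe sets. Because normexp added an offset of 50 back, the calls kept under it do not show that remaining background is unimportant. Among the genes no longer called after quantile normalization were AHSG and ANLN. The share of higher genes among those called, 89.5%, lay between 83.0% and 92.2% under other scalings, filters and probe set rules. With other fold thresholds it was 85.0% at 1.3-fold and 66.7% at 2-fold, where 12 genes were called. No paired analysis was possible because the control has 1 array. Background appears to remain in the intensities, which would limit what dim genes can show. Without the filter 0 genes below it passed the size rule, although limma passed more genes.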

Other observations

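In this part the hnRNP and peroxisome lists were chosen after the values were seen, while the tests of gene lists and chromosomes against gene density were set before their results were seen. The 19 measured genes for heterogeneous nuclear ribonucleoproteins (hnRNPs), proteins that bind nuclear RNA and act in splicing and mRNA handling, had medians of 0.26 in line 1 and 0.22 in line 2 (percentiles 99.95 and 99.67 among random lists). HNRNPK was 1.90-fold and 1.91-fold higher, HNRNPA2B1 1.64-fold and 1.63-fold, HNRNPH1 1.60-fold and 1.57-fold and HNRNPR 1.58-fold and 1.56-fold, and 0 were lower. In limma 8 of the 19 rose and 0 fell over all genes tested. The 7 other probe sets of these 4 genes had a median difference of 0.40, with 0 past 1.5-fold. These 4 genes prompted the list, so the percentiles and the limma count with them are no test of the group. The 15 hnRNP genes not called by size had medians of 0.15 and 0.12 and were not apart among genes not called (percentiles 93.9 and 89.1).

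Peroxisome genes were looked at because 5 of them, ABCD3 (1.85-fold and 1.77-fold), EHHADH (1.83-fold and 1.69-fold), PHYH (1.65-fold and 1.64-fold), AGPS (1.61-fold and 1.68-fold) and ACBD5 (1.58-fold and 1.57-fold), were among the higher genes. The whole list of 35 measured genes was not apart (medians 0.04 and -0.01, percentiles 88.5 and 55.2), although with the mean of all probe sets the percentiles over 31 genes were 99.3 and 98.3. Without the 5 genes that prompted it, the list of 30 was not apart among genes not called (percentiles 28.6 and 5.18). The 9 other probe sets of the 5 genes had a median difference of 0.09, with 0 past 1.5-fold.

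The differences from control ran along gene density. Genes with few neighbours had a median difference of 0.06 and those with many neighbours -0.09, and the correlation across genes was -0.34 in line 1 and -0.29 in line 2. Between the 2 lines the same correlation was -0.10. Altered copy number of whole chromosomes is argued against as the main source, because the correlation remained at -0.25 within chromosomes and was below 0 in 22 of 23 chromosomes. Background control probe sets fell with their number of G or C bases (rho = -0.98 over 23), so a difference in hybridisation of the control array along base composition is a candidate explanation, but a change in the cells along gene density cannot be excluded with 1 control array.

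The 5 lists apart in both lines were set against random lists matched on level, gene density and gene length. The trend along density and length is argued against as the cause for enterocyte brush border genes (percentile 0.13 in the less extreme line) and TGF-beta and BMP targets (1.15). For metallothioneins the percentile was 0.09, but the test cannot decide for this list. Their median length was 1.34 kb against 27.9 kb over all genes, which the broad length bins match poorly. Probes may also not separate these close sequence copies, while random lists count them as separate genes. For interferon-stimulated genes the less extreme percentile was 7.25, and for the AU-rich HuR targets 96.8, so for these the trend may account for part of the distance; in line 2 they stayed outside the bounds (0.01 and 97.65). Lower metallothionein and brush border levels after OCC-1 depletion are a hypothesis only, since culture density, hairpin delivery and the single control array were not separable here.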
